A study of Mus musculus with 12 samples.

How the data were processed

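RNA was measured in 12 libraries of 4T1 cells, a mouse mammary carcinoma line, grown as 3D cultures in collagen I. Per the labels' protocols, cells were nucleofected with Cas9 and either a control guide RNA or an ETV4 guide RNA, seeded in collagen, and grown in 2% serum for 4 days; the collagen was 1.2 mg/ml or 2.4 mg/ml, and the labels do not say which for each library. The FGF groups received FGF10 at 25 ng/ml and FGF2 at 40 ng/ml. Gels were digested with collagenase before RNA extraction, and libraries came from a stranded polyA protocol. The labels give 4 groups of 3 libraries: control, ETV4 knockout, control with FGF, and ETV4 knockout with FGF. All 6 knockout libraries carry the same further tag in their library names, whose meaning the labels do not give. The labels do not say whether the knockout cells were a pool or a single clone; of a single clone, clone and genotype could not be told apart. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

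The deposited table holds raw read counts per gene symbol, not normalized, for 31017 symbols. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.9a, featureCounts and R 4.1.1 were used, with the builds hg38 and mm10; mouse symbols fit mm10. The annotation release, strand setting and treatment of multi-mapping reads are not given in the sources used here, so counts of near-identical or overlapping genes are uncertain. Of the symbols, 13134 had no count in any library, and no row lacked a gene name. Coordinates are mm10, 1-based, from GENCODE vM21 gene models: 30477 symbols matched one model directly, 113 through an older symbol, 56 matched several models and 371 matched none.

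Library totals ran from 18229429 to 23193244 counts. No pair of libraries within a group was a duplicate: the chi-square per degree of freedom between replicates of a group was 3.34 or higher, where sampling noise alone gives about 1.

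Genes were tested with the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3, after filterByExpr by group and TMM scaling, with a mean per group over all 12 libraries and 8 residual degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 among the 12079 genes tested. Unless stated otherwise, every adjusted p of a gene is from this test. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are TMM-scaled. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison; 2 lists, of fibroblast and of macrophage and leukocyte markers, had 2 and 1 tested members and no set test. The same test was run with an estimated correlation, and fry was an alternative.

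The design, 36 gene lists and the rule for named genes were fixed before the data were examined. The rule names Etv4, Etv1 and Etv5; per comparison the 10 genes with the largest fold change in each direction among called genes with a mean log2 CPM of at least 1 and separated libraries; and up to 4 members per list with the smallest adjusted p. Predicted or unnamed genes were counted but not named. A fold against a group with 0 counts is a lower bound at a floor of 3 counts per group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Floors and intervals cover counting error only.

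Alternatives planned beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, a replicate block, fits on the compared libraries alone, a test against a log2 fold change of 1, removal of predicted genes, and leaving out each library. A correction of each library's trend with exon length and GC content, and a fit without both Etv4_KO replicate 2 and control_FGF replicate 2, were chosen after seeing the data. The trend was fitted to each library's deviation from the mean of all 12 libraries. A genotype or FGF effect that follows length or GC content is therefore removed with it. A call that changes after the correction does not by itself show a technical cause.

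The test was checked on simulated counts with 200 changed genes. For the knockout comparison without FGF, run on 11983 genes, it recovered 65.7% of 1.5-fold, 85.1% of 2-fold and 98.5% of 4-fold changes. With FGF, run on 11975 genes, the shares were 73.1%, 89.6% and 98.5%. For FGF in control cells, run on 11972 genes, the shares were 67.2%, 85.1% and 90.9%. For FGF in knockout cells, run on 11973 genes, they were 59.7%, 82.1% and 98.5%. For the interaction, run on 11982 genes, they were 23.9%, 77.6% and 97%. Camera called a simulated list raised 1.5-fold and 0 of 35 unchanged lists. False calls were 5 of 171 for the knockout without FGF and 12 of 186 with FGF. For FGF they were 10 of 172 in control and 8 of 168 in knockout cells, and for the interaction 2 of 134. All libraries were drawn with the same spread per gene, so none stood apart as Etv4_KO replicate 2 does. The real knockout comparisons also called far more genes than were changed here, so these shares need not hold for the real comparisons. The simulated genes were drawn independently, so this check does not cover correlation between the genes of a list.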

Results

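Gene expression was measured by RNA sequencing in 4T1 mouse mammary carcinoma cells grown in 3D collagen I, comparing cells that received Cas9 with a control guide against cells that received an ETV4 guide, each without and with FGF10 and FGF2. ETV4 is an ETS transcription factor of the PEA3 family, with Etv1 and Etv5 as the other members. Each of the 4 groups had 3 libraries. Replicates 1 to 3 held 20253458, 20284549 and 19461155 counts in control, 20108072, 18229429 and 21888600 in knockout, 23193244, 19485988 and 20198060 in control with FGF, and 22106904, 19434764 and 20821585 in knockout with FGF. The first principal component, with 71.4% of the variance, separated control from knockout libraries. The second, with 10.4%, separated Etv4_KO replicate 2 from the rest. In that library ribosomal protein genes took 6.74% of counts, against 4.96% and 5.2% in replicates 1 and 3, and its deviation from them had a Spearman correlation across genes of -0.55 with exon length and 0.57 with GC content. Genes are not independent replicates, so no p is given for these correlations.

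The targeted gene was examined first. Etv4 (mm10, chromosome 11, 101769742 to 101785371) was detected in every library: in replicates 1 to 3 at 167.9, 162.2 and 167.5 CPM in control, 116.3, 159 and 116 in knockout, 154.5, 173 and 166.9 in control with FGF, and 115.2, 119.5 and 113.1 in knockout with FGF. The means were 166 ± 3.18 CPM in control and 130 ± 24.8 CPM in knockout libraries (SD, n = 3 each), and with FGF 165 ± 9.44 and 116 ± 3.3 CPM (SD, n = 3 each). The decrease was 21.3% without FGF (log2 -0.35, SE 0.11, edgeR adjusted p = 0.0173) and 29.7% with FGF (log2 -0.51, SE 0.11, edgeR adjusted p = 0.00204). An exact two-sided permutation test gave p = 0.1 in both conditions, the smallest value possible with 3 against 3. Without Etv4_KO replicate 2 the change without FGF was log2 -0.51 (edgeR adjusted p = 1.14e-07). Without control replicate 1, Etv4_KO replicate 1 or Etv4_KO replicate 3, the call without FGF was lost (edgeR adjusted p = 0.0514, 0.0661 and 0.0667). A guide-induced mutation need not lower the transcript, so the level does not test the loss of the protein. Genes around Etv4 on chromosome 11 were shifted by a similar amount: the median log2 fold change of its neighbours, 25 expressed genes on each side, was -0.36 without and -0.46 with FGF. Etv5 (chromosome 16, 22381309 to 22439719) fell from 61.6 ± 0.998 to 32.9 ± 2.65 CPM without FGF (log2 -0.90, SE 0.07, edgeR adjusted p = 8.99e-07) and from 68.8 ± 0.234 to 33 ± 1.42 CPM with FGF (log2 -1.06, SE 0.07, edgeR adjusted p = 1.98e-07; SD, n = 3 each). Its neighbours had a median of -0.31 in both conditions. Etv1 did not pass the test in either condition (log2 -0.07, SE 0.13, and 0.09, SE 0.13). Without FGF its sign turned without Etv4_KO replicate 2 (0.11, edgeR adjusted p = 0.156) and after the length and GC correction chosen after seeing the data (0.185, edgeR adjusted p = 0.0162).

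**Figure D1:**
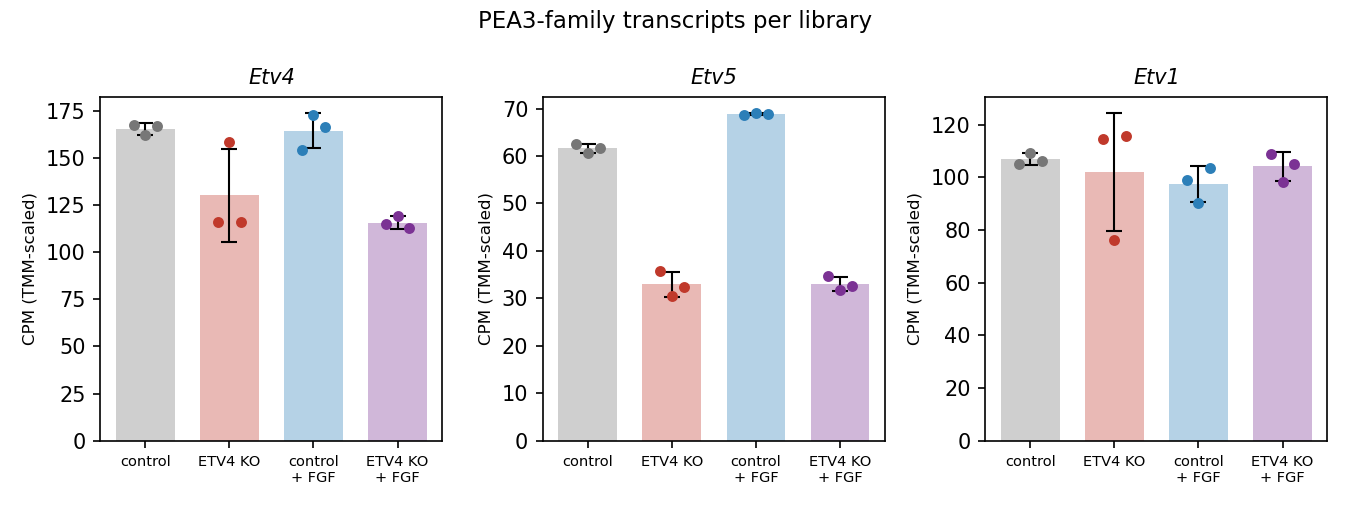
TMM-scaled CPM of Etv4, Etv5 and Etv1 in each library of the 4 groups; bars are group means, error bars are SD (n = 3) and points are libraries. Etv5 lies at 32.9 CPM on average in knockout libraries without FGF against 61.6 CPM in control, and Etv4_KO replicate 2 holds more Etv4 (159 CPM) than the other two libraries of its group.

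The comparison of knockout with control cells without FGF asks what differs with the ETV4 guide at baseline. The largest decreases included Cav1, the main structural protein of caveolae, Rab25, a GTPase of epithelial recycling endosomes, and Cldn7, a tight junction claudin. Cav1 (chromosome 6, 17306335 to 17341452) fell from 36.7 ± 1.77 to 0.293 ± 0.21 CPM (log2 -6.86, SE 0.26, edgeR adjusted p = 8.1e-10), and Cldn7 (chromosome 11, 69964779 to 69967885) from 181 ± 3.98 to 3.86 ± 0.684 CPM (log2 -5.55, SE 0.13, edgeR adjusted p = 2.25e-11; SD, n = 3 each). Rab25 fell by 6.19 on the log2 scale. Rnase4, Otop1, Rps6ka6, Slc39a4, Sox15, Spata13 and Tubb2b made up the rest of the 10 largest decreases, between log2 -5.49 and -4.71. The largest increases were in Tnxb, an extracellular matrix tenascin (log2 5.20, SE 0.32), Pla2g4e (4.53, SE 0.27), the secreted peptidase Klk10 (3.52, SE 0.14), the cadherin Cdh23 (3.43, SE 0.18) and the caveolar protein Cavin2 (3.41, SE 0.13). Pcsk6, Anxa8, Gsta1, Pgbd5 and Sqor followed, at log2 3.28 to 2.77. In all, 2723 genes were higher and 2810 lower in knockout cells, 45.8% of the 12079 tested, and 298 and 895 of these differed at least 2-fold. Fitted on the libraries of these groups alone, 1805 were higher and 2097 lower.

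**Figure D2:**
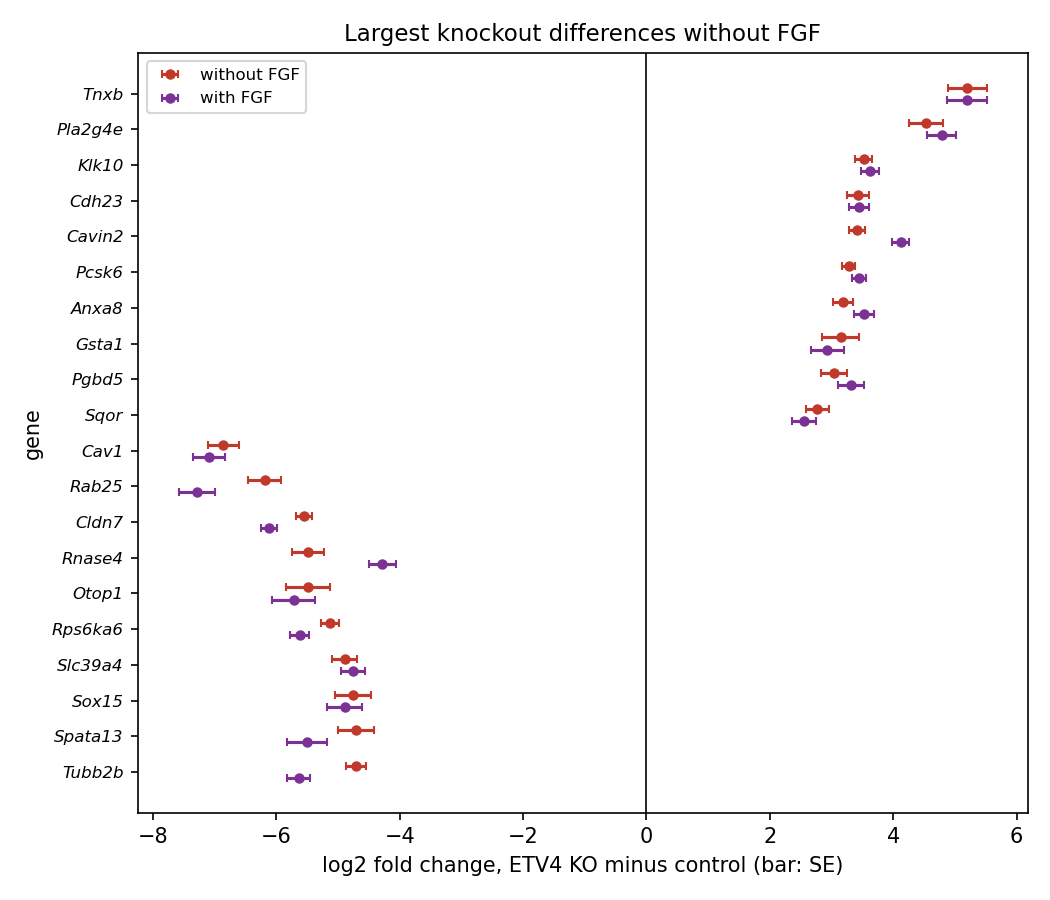
log2 fold change of knockout over control, without and with FGF, for the 10 largest increases and 10 largest decreases called without FGF; points are edgeR estimates and bars are SE. Each gene lies on the same side of 0 in both conditions, Cav1 at -6.86 and -7.09.

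Transcripts of most MHC class I presentation genes were lower in knockout cells. Of 18 tested genes of that list, 14 fell, 0 rose and 4 were not called, with the same counts adjusted over the list alone. Nlrc5, the transactivator of MHC class I genes, fell by 3.28 on the log2 scale (SE 0.14), H2-Q7 by 3.04 (SE 0.19), and the immunoproteasome subunits Psmb8 and Psmb9 by 2.58 (SE 0.20) and 2.98 (SE 0.24). Multigene families such as H2-Q7 share reads with close copies, so single members are uncertain. Of 25 cytokine, chemokine and NF-kB genes, 15 fell and 4 rose, and adjusted over the list alone the counts were the same; Il1a fell by 2.05 (SE 0.11), Vcam1 by 1.53 (SE 0.14) on the log2 scale, and Tnf was at log2 -3.61 (SE 0.33). Of 23 type I interferon response genes, 9 fell and 3 rose (12 and 3 adjusted over the list alone), Parp14 and Isg15 by log2 -1.92 and -1.28. Of 11 Wnt response genes, 8 fell and 2 rose, the same adjusted over the list alone, with the Wnt antagonists Sfrp1 and Notum at log2 -2.78 and -3.04 and Tcf7 at -2.39. Camera gave an adjusted p of 5.87e-06 for the MHC class I list , 0.0136 for cytokines, 0.0181 for the interferon list and 0.0136 for the Wnt list. With an estimated correlation these were adjusted p = 0.154, 0.134, 0.154 and 0.154. Without Etv4_KO replicate 2 the Wnt list no longer passed (camera adjusted p = 0.0531), nor did the interferon list without Etv4_KO replicate 3 (0.0629), and 1 interferon gene was higher without control replicate 1.

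More genes of the cell cycle, cholesterol and stress lists rose than fell. Of 25 G2 and M phase genes, 14 rose and 0 fell, including Cenpa (log2 0.66, SE 0.07) and Prc1 (0.57, SE 0.06), with the same counts adjusted over the list alone. Of 25 S phase genes, 13 rose and 1 fell (13 and 2 adjusted over the list alone), Rrm2 by 0.70 (SE 0.06). Of 23 cholesterol synthesis genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), including Cyp51 (0.55, SE 0.06). Of 22 integrated stress and unfolded protein response genes, 12 rose and 2 fell, Chac1 by 1.71 (SE 0.12) and the chaperone Hspa5 by 0.49 (SE 0.06). Of 18 NRF2 genes, 12 rose and 3 fell, with Hmox1 at 1.21 (SE 0.10) and Nqo1 at 1.10 (SE 0.10), and of 21 hypoxia genes 11 rose and 5 fell, Ndrg1 by 1.36 (SE 0.08). Counts adjusted over the list alone were the same for these last 3 lists. Of 12 basal keratinocyte-like genes, 8 rose and 3 fell, the same adjusted over the list alone, including the laminins Lama3 and Lamb3 (0.99 and 1.08). Camera adjusted p values were 0.00667 for both cell cycle lists, 0.00779 for cholesterol and for the stress response, 0.00799 for NRF2, 0.0181 for hypoxia and 0.0209 for the basal list. With an estimated correlation no list passed in this comparison, at adjusted p = 0.131 for G2 and M phase and for cholesterol, 0.236 for S phase, and 0.154 for the other 4. After the length and GC correction the hypoxia list missed (camera adjusted p = 0.0611). When Etv4_KO replicate 2 was left out, 2 G2 and M phase and 3 S phase genes were lower, and without any 1 library of Etv4_KO 2 cholesterol genes were. The mean of the hypoxia list, log2 -0.10, was opposite in sign to its median, 0.35, and its test.

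Nuclear-encoded oxidative phosphorylation (12 of 24 higher, 0 lower; 15 and 0 adjusted over the list alone) and glycolysis genes (11 of 18 higher, 2 lower; 13 and 2 adjusted over the list alone) were also higher by camera (adjusted p = 0.00779 and 0.0255; 0.624 each as adjusted p with an estimated correlation). Ndufv2 rose by log2 0.73 (SE 0.11) and Aldoa by 0.94 (SE 0.12), whereas Aldoc fell by 2.20 (SE 0.20). These lists moved with Etv4_KO replicate 2: their median log2 fold changes were 0.295 and 0.365 with it and 0.149 and 0.21 without it, where their camera adjusted p was 0.0545 and 0.059. Without control replicate 2, 5 oxidative phosphorylation genes were higher, and 1 was lower without Etv4_KO replicate 2. After the length and GC correction the glycolysis list also missed (camera adjusted p = 0.0671). The heat shock and dissociation list (9 of 20 higher, 4 lower, the same adjusted over the list alone; camera adjusted p = 0.0358, and adjusted p = 0.447 with an estimated correlation) included Dusp1 at 1.48 (SE 0.07) and Hsph1 at 1.15 (SE 0.06). Its median was 0.112, and 0.144 without that library, where it also missed (camera adjusted p = 0.059). It missed after the length and GC correction too (camera adjusted p = 0.334).

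Among FGF pathway genes the knockout cells differed in both directions. The receptor Fgfr1 (chromosome 8, 25513654 to 25575718) fell from 12.2 ± 1.8 to 1.57 ± 0.061 CPM (log2 -2.96, SE 0.18, edgeR adjusted p = 7.05e-08; SD, n = 3 each), and the FGF carrier protein Fgfbp1 rose by 2.65 (SE 0.09). Gpc4, a glypican co-receptor, had 1 count in the knockout libraries, a ratio of 323 with a counting interval of 57.6 to 12800. Of 13 genes of the FGF receptor and ligand list, 4 rose and 5 fell, and of 24 ERK feedback genes 13 rose and 7 fell, each the same adjusted over the list alone, with Dusp5 at 1.39 (SE 0.08) and Spry1 at -0.78 (SE 0.08). Of 21 extracellular proteolysis genes, 12 rose and 5 fell, the same adjusted over the list alone, and of 18 reported PEA3-family targets 8 rose and 6 fell (9 and 6 adjusted over the list alone). The stromelysin Mmp3 rose by 1.24 (SE 0.06) and urokinase, Plau, by 1.01 (SE 0.05), while the tissue plasminogen activator Plat and its inhibitor Serpine2 fell, to log2 -2.11 (SE 0.09) and -3.90 (SE 0.21). None of these 4 lists passed camera as a whole (adjusted p = 0.62, 0.189, 0.0658 and 0.643), though the proteolysis list did without control replicate 1 (0.0468). The means of the proteolysis and PEA3 lists, log2 -0.05 and -0.32, were opposite in sign to their medians, 0.465 and 0.126. These lists share 6 tested genes. The epithelial junction list had 5 genes higher and 10 lower of 25, and the mesenchymal list 5 higher and 3 lower of 13. Neither passed (camera adjusted p = 0.283 and 0.704). Without control replicate 2, 5 PEA3 genes were higher, and 5 mesenchymal genes were lower without Etv4_KO replicate 2.

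With FGF present, knockout cells were again compared with control cells. Cav1, Rab25 and Cldn7 fell by 7.09, 7.29 and 6.12 on the log2 scale, and Tnxb, Pla2g4e and Cavin2 rose by 5.20, 4.79 and 4.12. Cp, Esyt3 and Mmp1b entered the 10 largest at -5.43, -4.78 and 2.93. Fgfr1 fell by 3.15 (SE 0.20) and Gpc4 was at least 125-fold lower. Of the MHC class I list 15 of 18 fell, 0 rose and 3 were not called, the same adjusted over the list alone, Nlrc5 by 2.96 (SE 0.14) and H2-Q7 by 3.62 (SE 0.20). In the stress response list 14 of 22 rose and 1 fell, and in the cholesterol list 14 of 23 rose and 1 fell (14 and 1, and 15 and 1, adjusted over the list alone). In the proteolysis list 12 of 21 rose and 4 fell, the same adjusted over the list alone; its mean, log2 -0.06, was opposite in sign to its median, 0.431, and its test. Camera adjusted p values were 1.47e-06 for MHC class I, 0.000199 for the stress response, 0.00133 for cholesterol and for heat shock, and 0.00442 for proteolysis, and no list passed with an estimated correlation (adjusted p = 0.117, 0.0971, 0.0971, 0.184 and 0.0971 in that order). In the NRF2, hypoxia, basal and heat shock lists 11, 13, 7 and 12 genes rose and 3, 3, 3 and 2 fell (11, 15, 7 and 13 higher and 3, 5, 3 and 2 lower adjusted over the list alone). Of 25 cytokine genes 14 fell and 3 rose (15 and 3 adjusted over the list alone), of 25 G2 and M phase genes 8 rose and 2 fell (9 and 2), and of 11 mitochondrially encoded genes 5 rose and 0 fell (6 and 0). Camera adjusted p values were 0.00442 for NRF2, 0.00471 for hypoxia, 0.0208 for the basal list and for cytokines, 0.0287 for G2 and M phase and 0.0171 for the mitochondrial list. With an estimated correlation they were adjusted p = 0.117 for NRF2, 0.499 for the mitochondrial list and 0.0971 for the other 4, and the mitochondrial list missed without Etv4_KO_FGF replicate 3 (0.056). Of the lists that passed without FGF, 5 missed here. In the S phase list 7 of 25 rose and 4 fell, in the interferon list 4 of 23 and 9, in the Wnt list 2 of 11 and 6 (each the same adjusted over the list alone, but 10 lower for interferon), in the oxidative phosphorylation list 2 of 24 and 2 (0 and 1), and in the glycolysis list 6 of 18 and 2 (7 and 2). Their camera adjusted p values were 0.284, 0.341, 0.0505, 0.579 and 0.303, and the mean of the glycolysis list, log2 -0.04, was opposite in sign to its median, 0.137. The Wnt list passed without any 1 of control replicate 1 or 2, Etv4_KO replicate 3, control_FGF replicate 1 or 3, or Etv4_KO_FGF replicate 1 or 2 (0.0325 to 0.0496), and with RLE scaling (0.048). When Etv4_KO replicate 2 was left out, 16 G2 and M phase genes were higher and 5 lower, 12 S phase, 7 oxidative phosphorylation and 6 cytokine genes higher, and 5 hypoxia genes lower. Without control_FGF replicate 3 or Etv4_KO_FGF replicate 1, 9 cholesterol genes were higher, and without control_FGF replicate 1 or 3 or Etv4_KO_FGF replicate 3 0 oxidative phosphorylation genes were. Without Etv4_KO_FGF replicate 2 or 3, 1 interferon gene was higher, and without Etv4_KO_FGF replicate 1 0 stress response genes and 1 heat shock gene were lower. The number of lower G2 and M phase genes was 1 without any 1 library other than Etv4_KO replicate 2 or 3, and that of lower oxidative phosphorylation genes 1 without any 1 library of control, control_FGF or Etv4_KO_FGF. In all, 2180 genes were higher and 2682 lower, 40.3% of those tested, and without Etv4_KO replicate 2 the counts were 3439 and 3733. That library is in neither group of this comparison, so it moves these counts through the fit shared by all 12 libraries. Fitted on the compared libraries alone, 6706 genes were called with FGF and 3902 without FGF. The order of the 2 conditions by count therefore depends on the estimate of spread. The median fold change of all genes was shifted by no more than 0.051 on the log2 scale by RLE or upper-quartile scaling.

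The knockout difference was largely shared between the 2 conditions. Across genes, log2 fold changes without and with FGF, which use separate libraries, had a Pearson r of 0.911 and a Spearman rho of 0.785. Of the called genes, 1646 were higher and 2030 lower in both, where 491.4 and 623.9 would overlap by chance, and 9 were called in opposite directions. Without Etv4_KO replicate 2 these counts were 2641, 2873 and 26.

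A further description of the knockout difference is by chromosome. The median log2 fold change of expressed genes was lowest on chromosomes 16 (-0.38 without and -0.35 with FGF) and 11 (-0.34 and -0.38), and highest on chromosome 17 (0.34 and 0.26). Medians over 189 windows of 50 neighbouring genes had a Pearson r of 0.922 between the conditions.

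**Figure D3:**
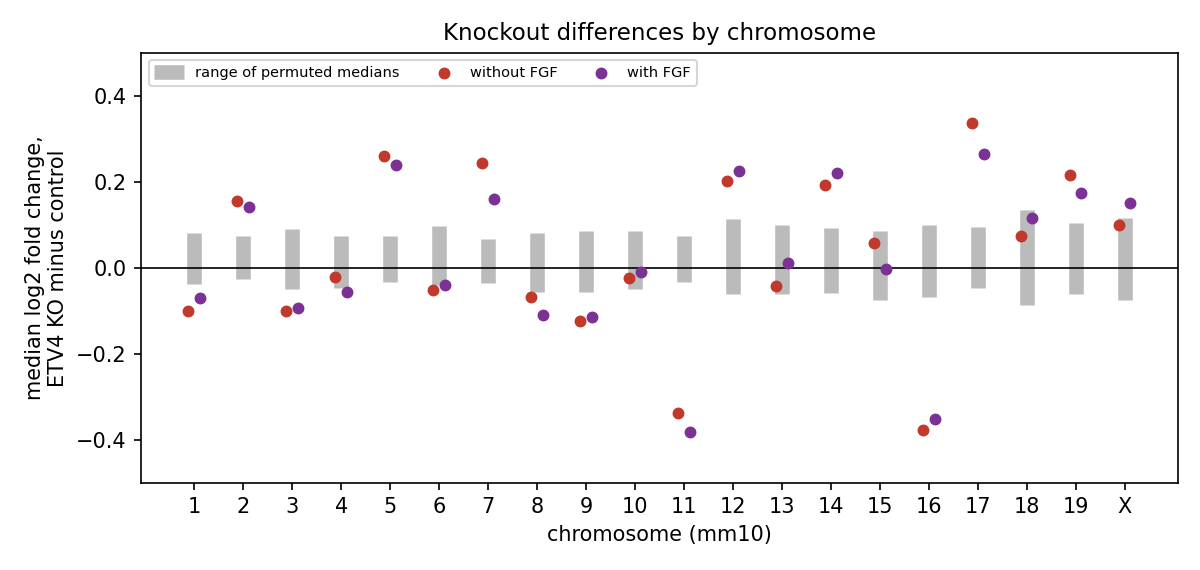
Median log2 fold change of knockout over control per chromosome, without and with FGF, for 9861 expressed genes; grey bars span the medians from 1000 permutations of gene positions without FGF. Chromosomes 11 and 16 lie lowest, at -0.34 and -0.38 without FGF.

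With FGF in control cells, the cytokine Csf2 rose from 3.64 ± 0.801 to 10.9 ± 0.893 CPM (log2 1.59, SE 0.20, edgeR adjusted p = 0.00149; SD, n = 3 each), and Rgs16, Sema7a, Tmem179 and Cdh17 rose by 1.08, 1.06, 0.97 and 0.96. Secreted proteases rose: Plau (chromosome 14, 20836660 to 20843385) by 0.68 (SE 0.05), Mmp10 by 0.64 (SE 0.07), Mmp9 by 0.56 (SE 0.08) and Mmp3 by 0.49 (SE 0.06). The largest decreases were Rgs2, which fell by 2.23 (SE 0.15), the nuclear receptors Nr4a2 and Nr4a1 (-1.83, SE 0.14, and -1.44, SE 0.10), and the immediate early genes Fosb, Fos and Klf4 (-1.32, -1.12 and -1.07). In all, 31 genes were higher and 28 lower, 5 and 9 of them at least 2-fold. The heat shock and dissociation list, which holds Fos and Klf4, had 6 of 20 lower and 0 higher (6 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.000701, and adjusted p = 0.187 with an estimated correlation). Gels were digested with collagenase before RNA extraction, and whether digestion differed between the groups was not tested. Over all genes the counts were 194 and 149 without Etv4_KO replicate 2, and 10 and 15 without control replicate 1. In a fit on the 6 control libraries alone they were 130 and 98. The call of Cdh17 was lost without control replicate 1 or 2 or control_FGF replicate 3 (edgeR adjusted p = 0.0749, 0.0604 and 0.0571), and that of Tmem179 without control replicate 1 or 2 or control_FGF replicate 1 or 2 (0.0749, 0.0922, 0.0631 and 0.0882).

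Of 21 proteolysis genes, 5 rose with FGF in control cells and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 1.45e-07, and adjusted p = 0.0178 with an estimated correlation). Of 24 ERK feedback genes, Phlda1 rose by 0.36 (SE 0.07) and 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 1.45e-07, and adjusted p = 0.0489 with an estimated correlation). The cholesterol list had 0 called genes but shifted upward as a list, with a median of log2 0.07 (camera adjusted p = 0.00112, and adjusted p = 0.0489 with an estimated correlation). Of 18 PEA3-family targets 3 rose and 0 fell, the same adjusted over the list alone, and of 13 EGFR and ERBB genes 2 rose, Errfi1 and Hbegf (5 higher and 1 lower adjusted over the list alone). Both passed camera (adjusted p = 0.0104 each), with adjusted p = 0.0781 and 0.187 under an estimated correlation. The PEA3 list, which shares 6 tested genes with the proteolysis list, missed after the length and GC correction (camera adjusted p = 0.0517). In the TGF-beta response list Id1, Id3 and Id2, targets of BMP signalling, fell by 0.85, 0.63 and 0.33, and Inhba rose by 0.40 (SE 0.07), so that 1 of 18 rose and 3 fell (2 and 6 adjusted over the list alone). This list did not pass camera (adjusted p = 0.0567), though it did without control replicate 2 or control_FGF replicate 3 (0.0255 and 0.0233). The collagen and matrix list (1 of 15 lower, 0 higher; 4 and 1 adjusted over the list alone) and the MHC class I list (0 of 18 called; 1 lower adjusted over the list alone) passed camera as lower (adjusted p = 0.0104 and 0.0137; 0.479 and 0.487 as adjusted p with an estimated correlation). The call of Phlda1 was lost without any 1 library of control, control_FGF or Etv4_KO_FGF (edgeR adjusted p = 0.0588 to 0.255) and after the length and GC correction (0.0625), and that of Errfi1 without any 1 of control or control_FGF (0.0539 to 0.116). That of Inhba was lost without any 1 of control, control_FGF or Etv4_KO_FGF (0.054 to 0.19). Those of Hbegf (0.0512 to 0.304) and Id2 (0.0571 to 0.275) were lost without any 1 library other than Etv4_KO replicate 2, that of Id2 also with RLE scaling (0.0554), and that of Id3 without control_FGF replicate 1 or 3 (0.0589 and 0.0539). With a replicate block the calls of Inhba, Hbegf and Id2 were also lost (edgeR adjusted p = 0.0575, 0.096 and 0.0928). By camera, the EGFR list missed without control replicate 3 or control_FGF replicate 1 (0.0755 and 0.0764), the collagen list without control replicate 1 or control_FGF replicate 3 (0.24 and 0.0622) and after the length and GC correction (0.117), and the MHC class I list without control_FGF replicate 1 or 3 (0.0694 and 0.0886). The basal list, with 2 of 12 higher and 0 lower (4 and 0 adjusted over the list alone), passed camera after the length and GC correction (adjusted p = 0.0278, against 0.0777 before it). Counts of called list members moved with single libraries. When Etv4_KO replicate 2 was left out, 9 ERK feedback, 5 PEA3, 5 EGFR, 4 basal, 3 heat shock, 2 TGF-beta genes and 1 collagen gene were higher, and 5 TGF-beta and 3 collagen genes and 1 gene each of the PEA3, EGFR and MHC class I lists lower. With any 1 library of control, control_FGF or Etv4_KO_FGF left out, 0 ERK feedback, basal and TGF-beta genes were higher, and with any 1 of control or control_FGF 0 EGFR genes. Without control replicate 1 or control_FGF replicate 1 0 collagen genes were lower, and without control_FGF replicate 1 or 3 1 TGF-beta gene was. Etv4 (-0.01, SE 0.11), Etv5 (0.16, SE 0.07) and Etv1 (-0.13, SE 0.13) were not called.

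In knockout cells FGF raised Slc7a11, the cystine transporter, by 1.63 (SE 0.22), Mmp9 by 1.52 (SE 0.08), Cdh17 by 1.44 (SE 0.15), Sema7a by 1.41 (SE 0.11) and Stc1 by 1.28 (SE 0.08). Fer1l6, Grid1, Nipal4, Tmem51 and the matrix glycoprotein Tnc also rose, by 1.38 to 1.18. The collagens Col6a2 and Col6a1 fell by 2.18 (SE 0.33) and 1.37 (SE 0.10), Igfbp7 by 1.47 (SE 0.23) and Rgs2 by 1.29 (SE 0.18). In all, 178 genes were higher and 114 lower. Without Etv4_KO replicate 2 the counts were 585 and 365, and without Etv4_KO_FGF replicate 2 they were 75 and 45. In a fit on the 6 knockout libraries alone they were 18 and 5, fewer than in control cells fitted the same way. Only the knockout fit holds Etv4_KO replicate 2. The call of Tmem51 was lost without Etv4_KO_FGF replicate 1 or 2 (edgeR adjusted p = 0.0548 and 0.0562).

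Of 21 proteolysis genes, 6 rose with FGF in knockout cells and 0 fell (8 and 1 adjusted over the list alone), including Mmp10 (1.14, SE 0.07), Plau (0.77, SE 0.05) and Mmp13 (1.12, SE 0.10). Of 20 adhesion and integrin genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), Itga5 by 0.58 (SE 0.07), Itgb1 by 0.44 (SE 0.07) and Itga2 by 0.90 (SE 0.15). Of 18 PEA3-family targets 4 rose and 1 fell (5 and 1 adjusted over the list alone), and of 25 G2 and M phase genes Nusap1 and Bub1b fell, by 0.29 and 0.28, and 0 rose (4 lower adjusted over the list alone). These 4 lists passed camera (adjusted p = 3.55e-05, 3.55e-05, 0.00156 and 0.00214) and held with an estimated correlation (adjusted p = 0.0354, 0.0354, 0.0388 and 0.0388). The proteolysis and PEA3 lists share 6 tested genes. The S phase list (2 of 25 lower, 0 higher; 11 and 0 adjusted over the list alone) passed camera at adjusted p = 3.55e-05, with adjusted p = 0.117 under an estimated correlation. The oxidative phosphorylation list, with 0 called genes, passed camera as lower (adjusted p = 0.00214) but not with an estimated correlation (adjusted p = 0.652) nor without Etv4_KO replicate 2 (camera adjusted p = 0.171). The calls of Nusap1 (edgeR adjusted p = 0.0554 to 0.156) and Bub1b (0.0632 to 0.157) were lost without any 1 library other than Etv4_KO replicate 2 and, for Nusap1, Etv4_KO replicate 3 or, for Bub1b, Etv4_KO replicate 1. Both were also lost with a replicate block (edgeR adjusted p = 0.0515 and 0.0673).

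Further lists passed camera for FGF in knockout cells without holding under an estimated correlation. Of 22 stress response genes 3 rose and 1 fell (9 and 2 adjusted over the list alone), of 23 cholesterol genes 2 rose and 0 fell (6 and 1), of 13 EGFR and ERBB genes 1 rose and 0 fell (3 and 0), and of 23 interferon genes 1 rose and 0 fell (2 and 0). Their camera adjusted p values were 0.00214, 0.00984, 0.00348 and 0.00214, and with an estimated correlation adjusted p = 0.117, 0.0624, 0.117 and 0.056. The glycolysis list, with 0 of 18 called (2 higher and 2 lower adjusted over the list alone), was lower (camera adjusted p = 0.0438; adjusted p = 0.652 with an estimated correlation). It missed without control replicate 2 (0.0514), Etv4_KO replicate 2 (0.29), control_FGF replicate 1 (0.0505) or Etv4_KO_FGF replicate 3 (0.0882), and after the length and GC correction (0.0611), and the cholesterol list missed without Etv4_KO replicate 3 (0.0828). After that correction the FGF receptor, basal and cytokine lists passed as higher (camera adjusted p = 0.0269, 0.0352 and 0.0334, against 0.153, 0.11 and 0.133). The corrected values were not tested with an estimated correlation. Without Etv4_KO replicate 2 the basal and fatty acid synthesis lists passed as higher (camera adjusted p = 0.0251 and 0.0206). The TGF-beta response list then passed as lower (camera adjusted p = 0.0238). Of 24 ERK feedback genes, Spred3 rose by 0.54 (SE 0.08), and Spry1 and Mafk fell by 0.63 (SE 0.08) and 0.36 (SE 0.08), so that 1 rose and 2 fell (2 and 2 adjusted over the list alone). This list did not pass camera (adjusted p = 0.265); when Etv4_KO replicate 2 was left out, 4 were higher and 2 lower and its direction turned to lower (0.715). The call of Mafk was lost without any 1 library of control or Etv4_KO_FGF, or control_FGF replicate 1 or 3 (edgeR adjusted p = 0.0506 to 0.147).

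The counts of called list members for FGF in knockout cells also moved with single libraries. When Etv4_KO replicate 2 was left out, 8 stress response, 7 cholesterol, 5 interferon, 2 EGFR, 8 adhesion genes and 1 glycolysis gene were higher, and 5 S phase and 4 G2 and M phase genes and 1 gene each of the proteolysis, adhesion and glycolysis lists lower. With any 1 library of Etv4_KO_FGF left out, 1 stress response, 0 cholesterol, 0 interferon and 3 adhesion genes were higher and 0 S phase and 0 G2 and M phase genes lower. Lower G2 and M phase genes were also 0 without any 1 library of control or control_FGF, lower S phase genes without any 1 of control or control_FGF replicate 1 or 3, and higher interferon genes without control replicate 1 or 3 or any 1 of control_FGF. Without Etv4_KO replicate 1, 1 stress response and 2 EGFR genes were higher. Without Etv4_KO replicate 3 1 cholesterol gene was lower, without control_FGF replicate 2 1 glycolysis gene was higher, and without Etv4_KO_FGF replicate 2 or 3 0 PEA3 genes were lower.

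Whether the FGF response depends on ETV4 status was tested with the interaction. Mmp9 (chromosome 2, 164940780 to 164955850), a gelatinase, and Mmp13 (chromosome 9, 7272514 to 7283331), a collagenase, passed: FGF raised Mmp9 from 123 ± 4.16 to 181 ± 5.4 CPM in control cells and from 80.5 ± 7.69 to 230 ± 12.9 CPM in knockout cells, a log2 difference of 0.95 (SE 0.11, edgeR adjusted p = 0.0123; SD, n = 3 each). Mmp13 stood at 52.7 ± 2.87 and 54.4 ± 3.82 CPM in control cells without and with FGF, and at 33.6 ± 4.56 and 73.4 ± 4.86 CPM in knockout cells, a log2 difference of 1.08 (SE 0.14, edgeR adjusted p = 0.0243; SD, n = 3 each). These were the 2 genes called higher; 0 were lower by edgeR, with 1227 genes at an unadjusted p under 0.05, and DESeq2 called 42 higher and 24 lower. Without Etv4_KO replicate 2, 88 genes were higher and 32 lower, among them Slc7a11 (log2 1.65, SE 0.16, edgeR adjusted p = 2.02e-06), whereas leaving out control replicate 1 left 0 genes. The Mmp13 call was lost without any 1 library of control or control_FGF, or Etv4_KO_FGF replicate 1 or 2 (edgeR adjusted p = 0.0535 to 0.153), and that of Mmp9 without any 1 of control, control_FGF replicate 1 or 3, or Etv4_KO_FGF replicate 1 or 2 (0.0513 to 0.091). By camera, adhesion and integrin genes and interferon genes responded more positively in knockout cells (adjusted p = 0.000479 and 0.00488), and S phase, oxidative phosphorylation and glycolysis genes more negatively (adjusted p = 0.000479, 0.000479 and 0.026). None held with an estimated correlation (adjusted p = 0.124, 0.17, 0.329, 0.662 and 0.662 in that order), and glycolysis was lost without control replicate 2, Etv4_KO replicate 2 or Etv4_KO_FGF replicate 3 (camera adjusted p = 0.0603, 0.0647 and 0.0649), and interferon without Etv4_KO replicate 3 (0.0888). The median log2 interaction went from -0.24 to -0.11 for the oxidative phosphorylation list and from -0.25 to -0.10 for the glycolysis list when Etv4_KO replicate 2 was left out. The ERK feedback list (median -0.10, camera adjusted p = 0.0657, and adjusted p = 0.464 with an estimated correlation) passed without control replicate 1, Etv4_KO replicate 2 or control_FGF replicate 2 (0.0444, 2.13e-05 and 0.0275). Its median was -0.16 without Etv4_KO replicate 2, where 1 of its genes was higher and 4 lower and 4 adhesion and 2 interferon genes were higher, against 0 each with all libraries, and after the length and GC correction its camera adjusted p was 0.421. That correction, chosen after seeing the data, added calls in 7 lists. The corrected values were not tested with an estimated correlation. The stress response, heat shock, PEA3, proteolysis, cytokine and FGF receptor lists passed as more positive in knockout cells (camera adjusted p = 0.000351, 0.00411, 0.00519, 0.0219, 0.0281 and 0.043, against 0.0926, 0.234, 0.119, 0.171, 0.313 and 0.427 before it), and the G2 and M phase list as more negative (0.00363, against 0.0657). The stress response and G2 and M phase lists also passed when Etv4_KO replicate 2 (0.00133 and 0.00165) or control_FGF replicate 2 (0.0275 each) was left out, and heat shock when control_FGF replicate 2 was (0.045).

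**Figure D4:**
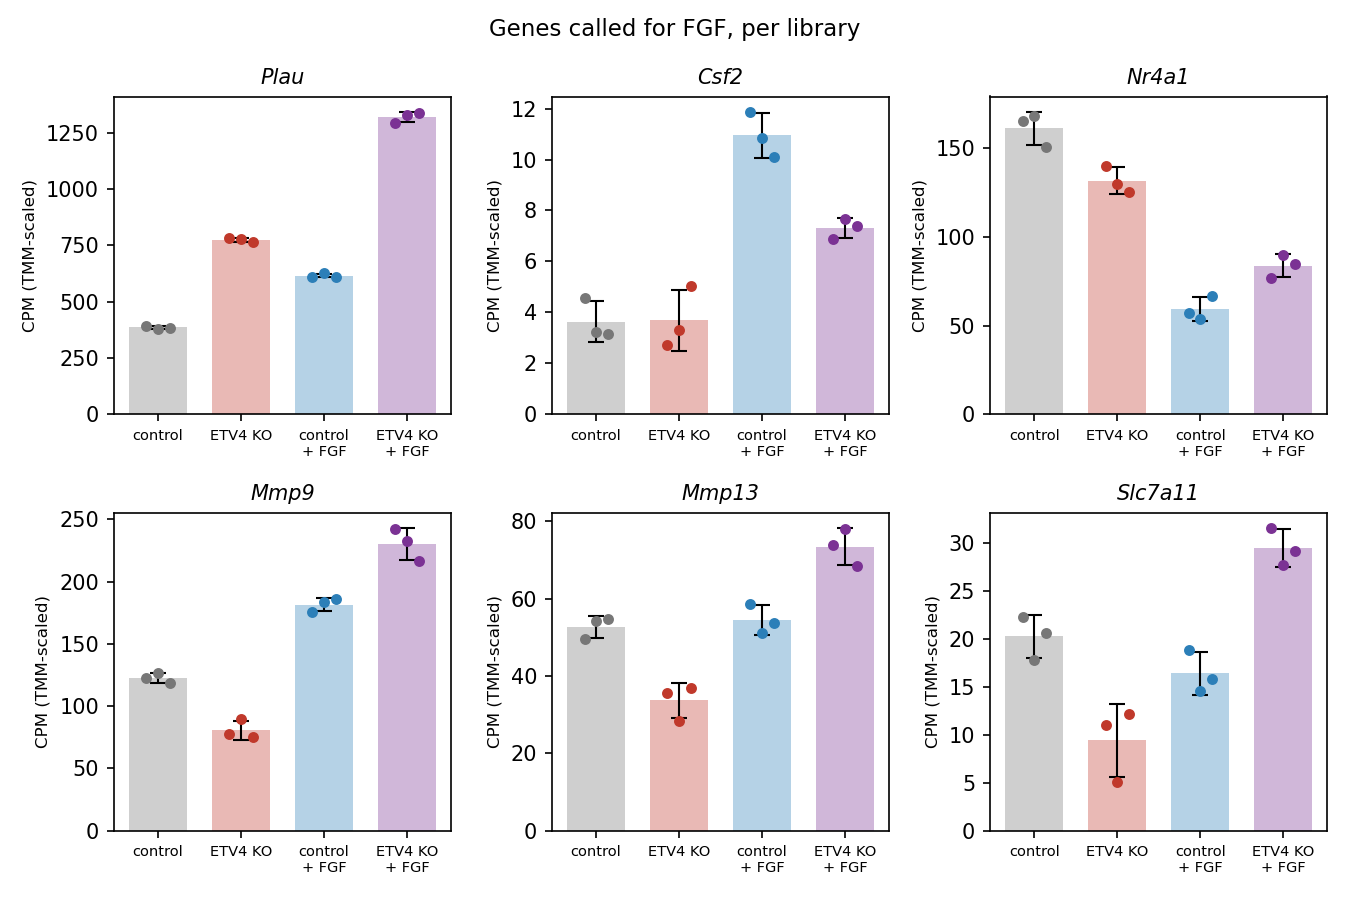
TMM-scaled CPM of 6 genes called for FGF in control or knockout cells, in each library of the 4 groups; bars are group means, error bars are SD (n = 3) and points are libraries. Mmp9 rises to 181 CPM with FGF in control cells and to 230 CPM in knockout cells, which start lower at 80.5 CPM.

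The FGF-responsive genes of control cells partly recurred in knockout cells and overlapped the knockout difference. Called in both genotypes were 22 higher and 18 lower genes, where 0.5 and 0.3 would overlap by chance, and 0 were called in opposite directions. Without Etv4_KO replicate 2 they were 125 and 63, without control replicate 1 10 were higher, and without control_FGF replicate 1 8 were lower. Across all genes, most of them not called for FGF, the FGF fold changes of the 2 genotypes had a Pearson r of 0.129 and a Spearman rho of -0.003. Of the 311 genes called for FGF in control or knockout cells, 269 had the same sign in both. Of the 31 genes raised by FGF in control cells, 20 were also higher in knockout than control cells with FGF and 7 lower, where 5.6 and 6.9 would overlap by chance; Plau was among those higher in both. Of the 28 lowered genes, 10 were lower and 8 higher in knockout cells, against 6.2 and 5.1 by chance. The genes higher in both ran from 7 without control_FGF replicate 1 to 105 without Etv4_KO replicate 2. These comparisons share the control libraries with FGF. Across genes their fold changes had a Pearson r of 0.027 and a Spearman rho of 0.021, and a covariance of 0.00607, where simulated unchanged groups sharing those libraries had a median Pearson r of -0.487 and a median covariance of -0.0209. Against the knockout difference without FGF, a comparison added after seeing the data, 19 of the 31 raised genes were higher and 6 lower (7 and 7.2 by chance), and 16 of the 28 lowered genes were lower and 4 higher (6.5 and 6.3 by chance). Without control replicate 1 these 4 counts were 7, 2, 10 and 1, and without Etv4_KO replicate 2 they were 114, 50, 90 and 27. The fold changes had a Pearson r of 0.211 and a Spearman rho of 0.314, and a covariance of 0.0488, where simulated unchanged groups sharing the control libraries without FGF had a higher median r, 0.503, and a lower median covariance, 0.0217. The simulated groups gave at most 1 call in any of these comparisons, so they give no reference for the counts of genes called in both. They held no knockout or FGF effect, whereas the observed fold changes do, so the observed and simulated r are not on a like scale. Their spread was estimated over all 12 libraries, Etv4_KO replicate 2 included. The simulated covariance may therefore differ from that given by noise in the control libraries alone. The controls were too few to split. Noise in the shared control libraries with FGF pushes the 2 fold changes to opposite signs. Part of the 7 and 8 opposite calls there may come from it, and it works against the 20 and 10 in the same direction. Noise in the shared control libraries without FGF pushes the fold changes to the same sign, so part of the 19 and 16 same-direction calls may come from it.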

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

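The tests in this part of length and GC content as part of a library's deviation, of mixed cells, of copy number as part of the difference, and of the FGF counts were chosen only after the results were seen. Results were looked at again where the FGF effect differed between genotypes by the interaction test. These were Mmp13 (log2 interaction 1.08) and Mmp9 (0.95), and the lists of S phase genes (median log2 interaction -0.164), type I interferon response genes (0.304), glycolysis genes (-0.248), nuclear-encoded oxidative phosphorylation genes (-0.236) and adhesion and integrin genes (0.37). None of these lists passed with an estimated correlation (adjusted p = 0.329, 0.17, 0.662, 0.662 and 0.124 in that order). The medians of the glycolysis and oxidative phosphorylation lists were -0.099 and -0.108 without Etv4_KO replicate 2, with camera adjusted p = 0.0647 and 0.00977. For the count of interaction genes, 7 of 100 splits of the libraries within genotype, the real one included, gave at least 2 genes. The 6 others kept the FGF states of 1 or both genotypes apart, so they carry an FGF effect, and the 80 splits that mixed the FGF states of both genotypes gave 0 genes each; the count of splits does not settle whether chance gives 2 genes. The highest other split gave 293 genes; it exchanges the FGF labels in 1 genotype, so it follows the FGF treatment of the libraries and tests the sum of the FGF effects.

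The first pattern is Etv4_KO replicate 2, which stands apart from its group. The SD over 9902 genes of its deviation from the rest of the group was 0.482, and removing each library's trend with exon length and GC content lowered this by 26.5%, so the trend may account for part of the deviation. It was not the whole of it as modelled: the SD stayed at 0.355, against at most 0.213 in the other 11 libraries. Control-guide cells mixed into the library were argued against, since 10 genes near 0 in the knockout libraries with FGF stood at 0.382% of their control level in it, against 0.369% and 0.469% in replicates 1 and 3. What makes up the rest stays open, and no biological explanation was tested. A trend in the same direction was seen in control_FGF replicate 2. Its deviation from the rest of its group had a Spearman correlation of -0.497 with exon length and 0.277 with GC content. The SD of that deviation was 0.185, and the correction lowered it by 13.3%.

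The second pattern is that genes of whole chromosomes were shifted together in knockout cells. The medians of 13 chromosomes lay beyond all 1000 permutations of gene positions, the same way in both FGF conditions. A copy-number difference between the cultured lines is therefore a candidate explanation for part of the difference. Of the 50-gene windows on these chromosomes 94.8% shared their chromosome's sign. The windows hold the genes that set that sign, so a high share is partly built in. On the chromosomes not beyond the permutations it ran from 41.7% (chromosome 4) to 100% (chromosome 18). Length and GC content were argued against as the cause of the chromosome shifts. The SD of the chromosome medians without FGF stayed at 0.188 after correction, where the highest permuted value was 0.037. Copy-number shifts over runs of neighbouring genes were argued against as the whole difference. After removing the median of neighbouring genes, the number of calls without FGF was 79.4% of that before, with 3493 of 5533 shared. The log2 change was -5.32 for Cldn7 and -0.59 for Etv5. It was 0.01 for Etv4 (edgeR adjusted p = 0.954), whose fold was log2 -0.35 (SE 0.11) before, close to its neighbours' median of -0.36. A gain or loss of single genes leaves that median as it is, so such a focal change was not tested. The removed median was taken as free of error, which can add calls. The loss of ETV4 and any other difference between the lines cannot be separated by these libraries, so the biological explanation stays open and untested.

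The third pattern is that FGF called more genes in knockout cells (292) than in control cells (59), a ratio of 4.95. The order turned when each genotype was fitted on its own 6 libraries. Knockout cells then had 23 genes and control cells 228, a ratio of 0.1, so the estimate of spread shared by all 12 libraries stays a candidate. The knockout fit holds Etv4_KO replicate 2 and the control fit does not, and own-library fits without it were not run. The turned order therefore cannot tell the shared estimate from the spread of that library. With the spread shared, the ratio was 2.77 without Etv4_KO replicate 2 and 6.96 after the length and GC correction, which argues against each as the whole cause under that estimate alone. The part of that library in the spread stays open. A different FGF response with the loss of ETV4 and a difference between the lines were not tested by these counts and stay open, and the interaction test called 2 genes.

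Other splits of the libraries were counted for each comparison of 2 groups. The 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with the highest count each time: 5533, 4862, 59 and 292 genes for the knockout without and with FGF and for FGF in control and knockout cells, against 0 in the highest other split. Every other split puts libraries of both groups on each side, so a real group difference enters the spread within a side. The 0 calls therefore give no measure of what chance would call.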

How the results depend on the processing

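The length and GC correction and the fit without both Etv4_KO replicate 2 and control_FGF replicate 2 were chosen after seeing the data; the cause of a moved count was not tested unless given. RLE and upper-quartile scaling, the stricter filter and removal of predicted genes kept the counts of called genes within 1.5 times. Against a log2 fold change of 1, which is a stricter hypothesis, 121 genes were higher and 461 lower in knockout cells without FGF, 118 and 449 with FGF, 0 and 2 for FGF in control cells, 1 and 0 in knockout cells, and 0 higher for the interaction. On the compared libraries alone, where the spread is estimated from 6 libraries, the knockout without FGF gave 1805 higher, FGF in control cells 130 and 98, and FGF in knockout cells 18 and 5, so that the order of the FGF counts between genotypes turned. DESeq2 called 85 and 58 for FGF in control cells, 410 and 320 in knockout cells, 42 and 24 for the interaction, and 52 higher and 34 lower in both genotypes. With no filter the interaction gave 7 and 1 genes and the r of knockout effects was 0.5; limma-voom gave 1 lower gene for the interaction. With the length and GC correction FGF gave 64 and 52 genes in control and 478 and 329 in knockout cells, the interaction 16 and 4, both genotypes 47 and 32, opposite knockout calls 17, and FGF genes also called for the knockout 35 higher in both, 21 lower in both, 21 higher then lower and 17 lower then higher; for the knockout without FGF these were 34, 31, 20 and 9. Without both libraries, 3489 genes were higher in knockout cells with FGF, FGF gave 210 and 146 in control and 828 and 600 in knockout cells, and the interaction 144 and 66. Etv1, at log2 -0.07 for the knockout without FGF, turned to 0.185 (edgeR adjusted p = 0.0162) after the correction. By fry the mesenchymal list (adjusted p with the sign of the direction, -0.0484) without FGF and the FGF receptor list (-0.0107) with FGF were lower, opposite to their camera direction; neither passed camera.

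Leaving out 1 library at a time, higher and lower counts ran from 2178 to 3212 and 2313 to 3455 for the knockout without FGF, 1731 to 3439 and 2208 to 3733 with FGF, 10 to 194 and 15 to 149 for FGF in control cells, 75 to 585 and 45 to 365 in knockout cells, and 0 to 88 and 0 to 32 for the interaction. The highest of each was without Etv4_KO replicate 2. Knockout genes shared across FGF conditions ran from 1341 to 2641 higher, 1736 to 2873 lower and 6 to 26 opposite, with r from 0.878 to 0.909. FGF genes shared by both genotypes ran from 10 to 125 higher and 8 to 63 lower, with r from 0.064 to 0.161. FGF genes also called for the knockout ran from 7 to 105 higher in both, 5 to 73 lower in both, 1 to 54 higher then lower and 3 to 38 lower then higher; for the knockout without FGF, 7 to 114, 10 to 90, 2 to 50 and 1 to 27. Among list tests, 42 calls were lost with an estimated correlation. With fry, 7 list calls were lost and 35 gained. Those gained for the knockout without FGF included the FGF receptor list as lower (fry adjusted p = 0.000707). The ERK feedback, PEA3 and proteolysis lists were gained there as higher (fry adjusted p = 0.00319, 0.000564 and 1.07e-05). Over all single-library omissions, 315 of the tests of named genes lost their call and 26 gained one, and 22 of the list tests lost and 29 gained one. The replicate numbers did not pair the libraries over all 4 groups: 2 of 18 same-number pairs had a correlation of deviations over 0.1, the median was 0.0075, and 7 of 12 libraries correlated best with their own number. Both of those 2 pairs joined Etv4_KO and control_FGF libraries, so a structure shared by these groups stays open. The higher of them, 0.343, joined replicate 2 of each group, whose deviations both followed exon length and GC content in the same direction. Whether that trend gives the correlation was not tested. With a replicate block the counts were 2775 and 2930, 2240 and 2704, 26 and 26, 174 and 95, and 3 and 0, and the TGF-beta list passed for FGF in control cells (camera adjusted p = 0.0428). Of the tests of named genes, 9 lost their call with the block and 1 gained one. Depth and spread limit small changes: in simulated counts, where no library stood apart, 23.9% of 1.5-fold interactions were recovered.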

Other observations

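Several genes were close to absent from knockout cells. With 0 counts in all 6 knockout libraries and at least 1 CPM in every control-guide library there were 11 genes, and 0 the other way round; with at most 3 counts the numbers were 23 and 1. Examples, chosen after their values were seen, are Bspry (0 counts in knockout against 1482 in control-guide libraries), Rasef (0 against 1178), Kazn (0 against 577) and the dystrophin gene Dmd (0 against 542). Axon guidance and branching genes moved in both directions without FGF, with 7 of 22 higher and 10 lower, including Sema3b, which fell by 4.50 (SE 0.30), and Sema4b, which rose by 1.03 (SE 0.07). In the Notch list 3 of 11 rose and 4 fell, Jag2 by 1.15 (SE 0.10) and Notch3 was at log2 -2.10 (SE 0.20). Neither list passed camera (adjusted p = 0.296 and 0.704). Of the marker lists of other cell types, in knockout against control cells without FGF fibroblast markers had 1 of 2 tested genes lower (Fbln1, at least 31.5-fold), macrophage and leukocyte markers 1 of 1 higher (Cd68), and endothelial markers 1 of 3 higher (Eng). The call of Cd68 was lost without any 1 library other than control replicate 2, Etv4_KO replicate 3 and control_FGF replicate 3 (edgeR adjusted p = 0.0508 to 0.16) and after the length and GC correction chosen after seeing the data (0.208), and that of Eng without control replicate 2 or 3 (0.0962 and 0.0656). With FGF, 1 of 2 fibroblast markers was higher (Pdgfra, log2 0.51, SE 0.18) and 1 lower (Fbln1, at least 31.8-fold), and Cd68 (log2 0.42, edgeR adjusted p = 0.0729) and the 3 endothelial markers (median log2 -0.02) were not called. The Pdgfra call was lost without control_FGF replicate 1 or 2 or Etv4_KO_FGF replicate 1 or 3 (edgeR adjusted p = 0.0503, 0.151, 0.128 and 0.0927), Cd68 passed without control replicate 2 or Etv4_KO replicate 2 (0.0299 and 0.023), by DESeq2 (0.0499) and after the correction (0.0441), and Eng passed without Etv4_KO replicate 2 (0.0239). Without FGF, TGF-beta response genes had 9 of 18 higher and 4 lower, p53 response genes 7 of 16 higher and 3 lower, YAP and TAZ response genes 5 of 18 higher and 7 lower, and fatty acid synthesis genes 4 of 18 higher and 5 lower. Their camera adjusted p values were 0.182, 0.326, 0.917 and 0.62. With FGF the axon guidance, Notch, TGF-beta, p53, YAP and TAZ and fatty acid lists had 6, 3, 7, 5, 8 and 5 genes higher and 9, 5, 4, 1, 5 and 7 lower, and none passed camera (adjusted p = 0.788, 0.943, 0.247, 0.528, 0.752 and 0.965). The p53 list had 5 genes lower without Etv4_KO replicate 2, 0 lower without control_FGF replicate 2 or 3 or Etv4_KO_FGF replicate 1 or 3, and 3 higher without replicate 1 or 3 of either of these groups. The TGF-beta list had 2 genes lower without any 1 library of control_FGF or Etv4_KO_FGF replicate 1 or 2, and the YAP and TAZ list 5 higher without control_FGF replicate 2 or Etv4_KO_FGF replicate 1. The fatty acid list had 3 genes higher without control_FGF replicate 1 and 4 lower without control_FGF replicate 3 or Etv4_KO_FGF replicate 3.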
